A study of Mus musculus with 5 samples.

How the data were processed

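RNA sequencing libraries of mouse bone marrow-derived macrophages after 0, 4, 8, 12 and 24 h of LPS at 100 ng/ml were compared, with 1 library per time point, as the sample titles and time labels give them. The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of the library) with 2 decimals, with 1 column per library, per the file headers. Bowtie2, RSEM and the genome build GRCm38 are named in the submitters' processing notes, without versions or roles; the annotation and any filter are not given in the sources used here. FPKM from RSEM-type estimates are normalized to the library and transcript length, so a gene's value falls when others take a larger share of the reads, and reads that match several copies of a gene are divided by estimate.

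The table listed 13339 genes with identifiers and symbols. Of these, 12392 were above 0 in all 5 libraries, 822 were at 0 in 1 library and 125 in 2 libraries, always those of 4 h and 8 h, and 0 genes were at 0 in 3 or more. Genes silent in most libraries were thus not among those listed. In 20 rows the symbol had been turned into a date and was restored by gene identifier from a RefSeq table of the same build. Of the identifiers 13319 were in that reference, 13296 of them as protein coding.

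Differences were computed on log2(FPKM + 1), which understates the fold of low genes, and folds quoted are ratios of FPKM. No fold was given against a value of 0. Genes entered the counts with a mean of at least 1 FPKM over the 5 libraries (9795 genes; 3544 were below), and a gene counted as higher or lower from a 2-fold difference on the log2 scale. Since there were no replicates, no test or p-value was computed, and 8 pairs of libraries were described. Genes were named by a rule fixed before the data were examined: for 4 h and 24 h against 0 h the 10 largest log2 differences in each direction, for 24 h against 4 h the 8 largest and for adjacent times the 3 largest, each among genes of at least 10 FPKM in 1 of the libraries compared, and besides these Setd2 and, for each gene list, its 2 to 4 members with the largest differences and the largest in the opposite direction. Named outside this rule, after their values were seen, were Tnf, Il6, Osm, Ifnb1, Tlr4 and Idi1 at 4 h, Ash1l and Msr1 at 24 h, and the members of gene families given as other observations. A few genes that the rule names are not reported here.

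Gene lists, 36 in all, were fixed before the data were examined. They cover inflammatory cytokines, chemokines, negative feedback and components of TLR signalling, interferon-stimulated genes, antimicrobial and acute-phase effectors, immediate early genes, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, LXR targets, lipid uptake and storage, eicosanoids, sphingolipids, glycolysis, the TCA cycle, the respiratory chain, alternative activation, efferocytosis, lysosome and autophagy, MHC class I and class II, the cell cycle, H3K36 methylation, stress responses, NRF2 targets, hypoxia, reference genes, ribosomal proteins, and markers of macrophages, dendritic cells, neutrophils, lymphoid cells, mast cells, erythroid cells and stroma. For each list of at least 5 measured genes, the median difference was placed among the medians of 10000 random lists matched on mean expression in 20 bins, with the list's own genes left out. The percentile describes these libraries and is not a test. The 4 smaller lists got counts only. After the data had been seen, random lists were also matched on transcript length (10 bins of expression by 5 of length), taken as the longest protein-coding transcript of the symbol in GENCODE M21, which 96.8% of the genes over the filter had.

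The deposited FPKM give no depth. For genes with 1 annotated transcript of 400 to 2500 nt, low values were compared with whole multiples of the value of 1 read. With a length reduced by 40 nt, between 54.4% and 66.2% of 145 to 159 values per library were whole within the larger of 0.04 reads and the rounding of 0.005 FPKM, against 27.9% to 29.2% by chance, and the best step corresponded to 18.9 to 19.2 M reads (megareads). The chance rates hold for a fixed step and length reduction. Both were chosen for the best match, so the rate to expect by chance from such a choice is higher. The step was searched only within a fixed window, so depths outside that window were not tried. The depth is an estimate. Whole reads could not be recovered for most genes, and no count test was run. Counting intervals (95%, Poisson) are computed from this depth and cover counting error only.

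The counting and list steps were tested on simulated data for the comparison of 4 h with 0 h, with Poisson reads drawn at the 0 h values for both libraries and 200 genes changed, and 9602 genes passed the filter. The 2-fold threshold was reached by 17.5% of 63 genes changed 2-fold, 97.0% of 66 changed 4-fold and 100% of 64 changed 8-fold, and by 0 of 9409 unchanged genes. Of 200 random lists of 20 genes 5.00% fell outside the middle 95% of their own random lists, and 100% of lists shifted by 0.5 lay above that middle range. The simulation holds counting error only, not variation between cultures or the spread of real differences between genes. In the real comparison of 4 h with 0 h, the middle 95% of random lists for inflammatory cytokines spanned -1.10 to 0.28. A shift of 0.5 could lie inside such a range. The simulated 100% therefore does not say how often such a shift would stand out in these data.

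The alternatives tried were pseudocounts of 0.1 and 5, libraries centred on the median gene, libraries rescaled to equal totals, no filter and a filter of 5 FPKM, each list without each of its members in turn or by its mean, and the times of highest and lowest values without each library in turn. The removal of the length trend in 20 bins, and gene families taken by symbol, were added after the data had been seen. That removal gave each bin the same median in every library, so it also centred the libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.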

Results

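Transcripts were measured by RNA sequencing in mouse bone marrow-derived macrophages, phagocytes grown from marrow precursors of 8-week-old C57BL/6 animals during 5 days in medium with the growth factor M-CSF. The cells received lipopolysaccharide (LPS), a bacterial cell wall component sensed by the receptor TLR4, at 100 ng/ml, and RNA was taken at 0, 4, 8, 12 and 24 h. Each time point was 1 library, so there were no replicates and no test between times was possible. Every difference given here therefore compares a pair of libraries. No unstimulated cells kept for 4 to 24 h were among the samples, so time in culture and time in LPS were not separated. The sample labels name macrophages, except 1 protocol field that speaks of dendritic cells. The samples are labelled wild type, and Setd2-deficient cells were not among them. The table listed 13339 genes as FPKM, of which 9795 had a mean of at least 1 FPKM over the 5 libraries. Steps between the low values of short genes placed the depth at about 18.9 to 19.2 M reads per library (M, megareads). At this depth 1 FPKM on a 1 kb transcript stands for about 19 reads, with a 95% Poisson interval of 11.4 to 29.7 reads that covers counting error only.

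The series title concerns Setd2, the enzyme that places the trimethyl mark on lysine 36 of histone H3, in lipid metabolism and the resolution of inflammation. Setd2 (gene 235626; chromosome 9, 110532500 to 110618633, GRCm38) stood at 7.40 FPKM at 0 h, 8.40 at 4 h, 6.57 at 8 h, 8.13 at 12 h and 12.45 at 24 h. The 95% counting interval was 6.98 to 7.84 FPKM at 0 h and 11.9 to 13.01 at 24 h. On the log2(FPKM + 1) scale the 24 h library was 0.68 above the 0 h library and 0.52 above the 4 h library. Setd2 has a long transcript (8350 nt), and with the trend by gene length described next removed, its difference between 24 h and 0 h was 0.28. At 8 h the difference from 0 h was -0.15. Once libraries were centred on their median gene, Setd2 was above 0 h by 0.74 at 4 h, 0.31 at 8 h, 0.42 at 12 h and 0.73 at 24 h, so that 24 h was not above 4 h on that scale. Of 19 measured enzymes and readers of H3K36 methylation, 2 were at least 2-fold higher and 3 at least 2-fold lower at 24 h than at 0 h. Their median difference of 0.39 (0.12 as a mean) lay at percentile 99.3 among 10000 random lists matched on mean expression. The 17 members with a known transcript length had a median of 0.26, at percentile 81.0 among lists matched also on length. For these 17 the median was 0.12 with the length trend removed. Whsc1l1, a methyltransferase of the Nsd family (36.4 FPKM at 24 h against 15.3 at 0 h), and the methyltransferase gene Ash1l (6.81 against 2.83) were higher. The methyltransferase gene Smyd2 (2.86 against 17.4), the DNA methyltransferase gene Dnmt3a (11.5 against 36.05) and the demethylase gene Kdm2b (3.08 against 9.55) were lower.

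The 0 h library stood apart from the 4 stimulated libraries. Across genes, which are not independent replicates, Spearman's rho on FPKM was 0.721 between 0 h and 4 h and 0.802 between 0 h and 24 h, against 0.947 between 4 h and 8 h, 0.974 between 8 h and 12 h, 0.952 between 12 h and 24 h and 0.858 between 4 h and 24 h. The median gene was lower at 4 h than at 0 h by a log2 difference of -0.70, and the difference from 0 h was -0.49 at 8 h, -0.35 at 12 h and -0.11 at 24 h. Lists of genes are therefore set beside the median of random lists in what follows. The shift went with gene length: at 4 h the 10% of genes with the shortest transcripts had a median difference from 0 h of -1.29 and the 10% with the longest -0.06. At 24 h these values were -0.78 and 0.34. Between 4 h and 24 h they were 0.42 and 0.40.

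**Figure D1:**
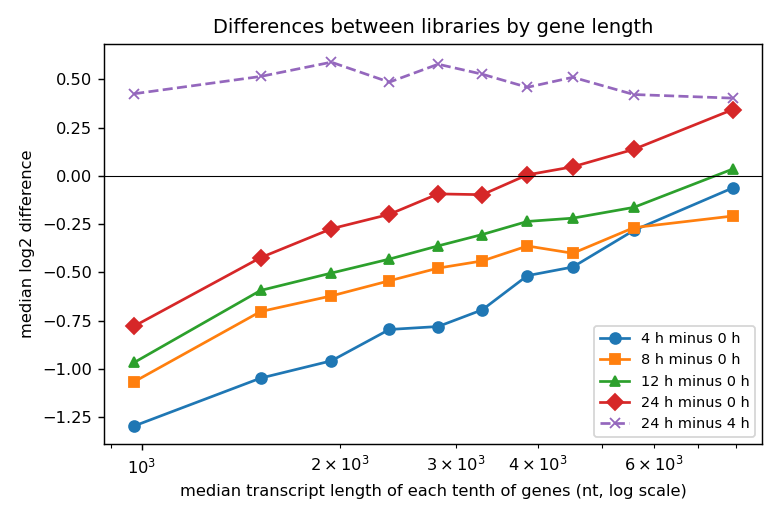
Median log2(FPKM + 1) difference between libraries (vertical axis) for each 10% of genes ordered by transcript length (horizontal axis, nucleotides, log scale); each line is a pair of libraries. The lines against 0 h lie higher for long genes, from -1.29 to -0.06 at 4 h, whereas the line of 24 h minus 4 h starts at 0.42 and ends at 0.40.

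The comparison of 4 h with 0 h addresses the early response to LPS. Inflammatory cytokines, chemokines, interferon-stimulated genes and the inhibitors of TLR signalling were far higher at 4 h than at 0 h. Lysosomal and antioxidant genes were lower relative to other genes. Il1b, the precursor of a pyrogenic cytokine, was at 2.5 FPKM at 0 h and 2323 at 4 h, a 929-fold difference. The chemokine gene Cxcl10 was at 8.09 at 0 h and 5616 at 4 h, and Acod1, which encodes the enzyme that makes itaconate, at 4.63 and 3121. Il27, a cytokine subunit, stood at 1.26 and 993 FPKM, Ptgs2, the inducible cyclooxygenase, at 0.55 and 658, the guanylate-binding protein gene Gbp5 at 1.87 and 1113, the collagenase gene Mmp13 at 3.08 and 1473, the vasoconstrictor gene Edn1 at 0.15 and 342, and Il1a at 1.25 and 586. Ifi205 had 2.04 and 1151 FPKM, and Gbp5 and Ifi205 belong to families of similar genes whose reads may be divided among copies, so their values are uncertain. Of 16 measured inflammatory cytokines, 15 were at least 2-fold higher at 4 h, with a median log2 difference of 5.36, above all 10000 random lists (median -0.50). Tnf stood at 9.93 and 2183 FPKM, Il6 at 0.10 and 247 and Il12b at 0.62 and 376, whereas Osm was at 4.01 and 4.10. Ifnb1 was listed at 0 at 0 h and at 7.87 FPKM at 4 h. Among 16 chemokines 14 were at least 2-fold higher (median 6.13), including Cxcl2 with 2.11 and 608 FPKM and Ccl5 with 22.0 and 4730.

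Genes that restrain the response were higher at 4 h too: 18 of 19 measured negative regulators of TLR signalling were at least 2-fold higher than at 0 h, with a median of 4.12, above all random lists. Socs3, an inhibitor of cytokine receptor signalling, had 2.71 and 763 FPKM, the ubiquitin-editing gene Tnfaip3 6.94 and 548, and the receptor antagonist gene Il1rn 12.7 and 893. Interferon-stimulated genes had a median difference of 4.74, and 29 of 30 were at least 2-fold higher, with Rsad2 at 14.7 and 3928 FPKM and Cmpk2 at 8.27 and 2039. Antimicrobial and acute-phase genes had a median of 3.30 (15 of 19 at least 2-fold higher), and both of these lists lay above all random lists. TLR signalling components had a median of 0.78 (percentile 99.9), but went both ways: Tlr3, a receptor for double-stranded RNA, was at 2.81 and 33.3 FPKM and Cd14, the LPS co-receptor, at 170.5 and 931, while Tlr13 was at 101 and 14.3 and Tlr4 itself at 19.1 and 6.01. The median of the TLR components was 1.36 with libraries centred on the median gene and 1.41 with the length trend removed. MHC class I presentation genes had a median of 1.13 (percentile 98.1; 1.71 and 1.91 under these scalings) with 7 of 13 at least 2-fold higher, including Tap1 with 23.4 and 267 FPKM. Of 14 immediate early genes, 4 were higher and 3 lower, with a median of 0.38 (percentile 99.6), and of 0.96 and 1.29 under these scalings. Junb stood at 58.2 and 346 FPKM, and Egr2 at 17.9 and 1.46.

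The genes with the largest negative difference at 4 h included Cxcr4, a chemokine receptor (142 FPKM at 0 h and 1.31 at 4 h), Tmem86a (71.0 and 0.39), the stress-response gene Sesn1 (64.8 and 0.35), the myeloid receptor gene Cd300lb (120.4 and 1.75), Rab7b, a small GTPase of late endosomes (97.9 and 1.65), Arhgap19 (47.0 and 0.32), and the transcription factor genes Lyl1 (64.5 and 1.04) and Cebpa (94.0 and 2.04). Slc26a11 (34.4 and 0.20) and Arl11 (112 and 3.14) completed the set of 10. Lysosome and autophagy genes had a median of -1.09, at percentile 0.37 (random median -0.34). The median was -0.50 with libraries centred on the median gene and -0.48 with the length trend removed. Tfeb, a regulator of lysosomal gene expression, was at 48.6 and 1.32 FPKM. NRF2 targets had a median of -1.11 (percentile 1.16), with Hmox1, heme oxygenase, at 176.5 and 44.2 FPKM; their median was -0.53 when centred and -0.28 with the length trend removed. In all, 1197 genes were at least 2-fold higher and 3729 at least 2-fold lower at 4 h than at 0 h, so 24.3% of the genes apart were higher. The split depended on scaling: 1903 were higher and 1598 lower (54.4% higher) once libraries were centred on the median gene, and 1776 and 1259 (58.5%) once the length trend was removed.

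**Figure D2:**
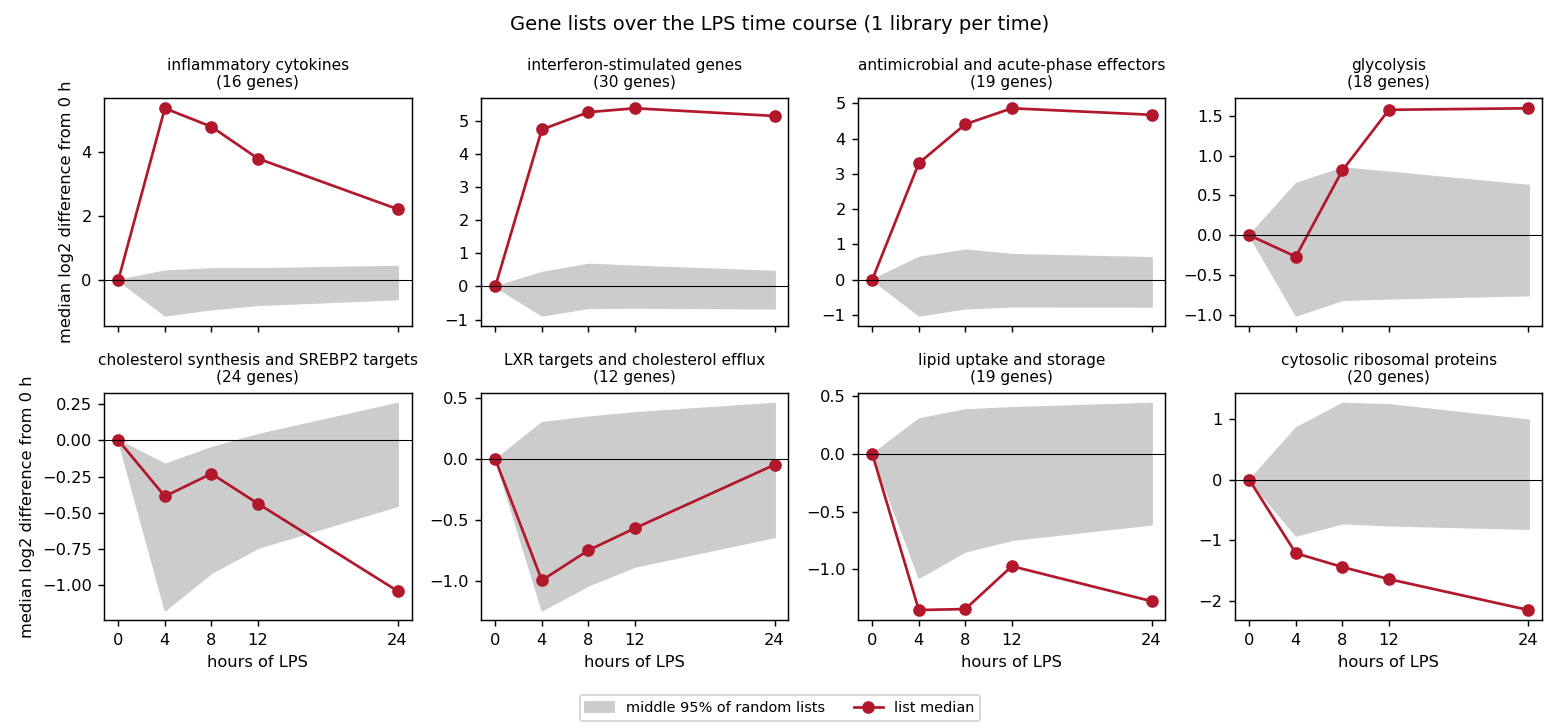
Median log2(FPKM + 1) difference from 0 h (vertical axis) of 8 gene lists at each time in LPS (horizontal axis, hours), 1 library per time; red points are list medians and the grey band spans the middle 95% of 10000 random lists matched on mean expression. Inflammatory cytokines stand at 5.36 at 4 h and 2.21 at 24 h, interferon-stimulated genes at 4.74 and 5.14, and cholesterol synthesis genes at -0.39 and -1.04.

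The comparison of 24 h with 0 h addresses the late state under LPS. Acute-phase, antimicrobial and interferon-stimulated genes had the largest positive differences. The glycolysis, hypoxia and antioxidant lists had positive medians too. The lists of apoptotic cell uptake, lipid uptake, cholesterol synthesis and ribosomes had negative ones. Of 19 lipid uptake and storage genes, 10 were at least 2-fold lower but 6 at least 2-fold higher. Of 24 cholesterol synthesis genes, 13 were at least 2-fold lower and 11 within 2-fold. Saa3, an acute-phase serum amyloid, stood at 18.7 FPKM at 0 h and 40998 at 24 h, where it alone made up 8.42% of the summed FPKM. Nos2, inducible nitric oxide synthase, had 0.32 and 761 FPKM, the chemokine gene Ccl5 22.0 and 12779, the complement gene Cfb 1.80 and 1148, Acod1 4.63 and 2145, Cxcl10 8.09 and 1364, the antiviral gene Rsad2 14.7 and 1993, and Slfn4, of the Schlafen family, 0.86 and 567. H2-Q8 was listed at 0 at 0 h and at 157 FPKM at 24 h, and Ifi205 had 2.04 and 347. Both belong to multigene families, so reads of close copies could count towards them. All 30 interferon-stimulated genes were at least 2-fold higher at 24 h than at 0 h, with a median of 5.14, and 15 of 19 antimicrobial and acute-phase genes were, with a median of 4.67. Cytokines (median 2.21, and 1.04 and 3.53 with pseudocounts of 5 and 0.1), chemokines (3.79) and negative regulators of TLR signalling (2.57) also lay above all random lists at 24 h. TLR components (0.44, percentile 98.7) and MHC class I genes (1.14, percentile 98.5) were likewise high among random lists.

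The lists of sugar metabolism and of the hypoxia and antioxidant responses had positive median differences at 24 h against 0 h. Of 18 glycolysis genes 14 were at least 2-fold higher, with a median of 1.60 (percentile 99.95). The lactate exporter gene Slc16a3 had 17.4 and 230.0 FPKM, the kinase gene Pfkfb3 8.47 and 201, and Slc2a1, a glucose transporter, 15.2 and 124. Hypoxia-response genes had a median of 1.26, above all random lists, with Egln3, an oxygen-sensing prolyl hydroxylase, at 0.40 and 20.3 FPKM and Bnip3, a mitophagy receptor, at 9.79 and 100.1. NRF2 targets, which serve antioxidant defence, had a median of 1.04 (percentile 99.7), with Hmox1 at 176.5 and 3228 FPKM and Slc7a11, a cystine importer, at 3.44 and 42.2. TCA cycle genes had a median of -0.57 (percentile 1.04) and nuclear-encoded respiratory chain genes of -0.74 (percentile 0.31), with no member of either list at least 2-fold higher. Against lists matched also on length these percentiles were 4.00 and 12.7, inside the middle 95%, and with the length trend removed the respiratory chain median was -0.30. In the TCA list Idh1, which encodes cytosolic isocitrate dehydrogenase, was at 163 and 31.3 FPKM, and in the respiratory chain list Cox4i1, a cytochrome oxidase subunit, at 520 and 149.

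The largest negative differences at 24 h included Lpl, lipoprotein lipase (974 FPKM at 0 h and 22.1 at 24 h), Clec7a, the receptor for fungal glucans (457 and 10.1), Atp6v0d2, a proton pump subunit (286 and 6.20), Crip1 (371 and 7.94), Pcp4l1 (58.1 and 0.58), the calcium-binding protein gene S100a4 (349 and 11.1), Igfbp4 (125 and 3.39), the cell cycle inhibitor gene Cdkn1c (247 and 7.67), Hpgd, a prostaglandin-degrading enzyme (28.4 and 0.03), and Ngp, a neutrophil granule gene (35.1 and 0.28). Efferocytosis receptors and bridging molecules, which take up dying cells, had a median of -1.39, below all random lists (median -0.07), with 11 of 17 at least 2-fold lower. Gas6, a bridging ligand, was at 235 and 19.3 FPKM and Mfge8 at 599.8 and 79.4, while Cd300lf was at 11.4 and 69.2. Markers of alternative activation and repair had a median of -1.30, also below all random lists. Mrc1, the mannose receptor, stood at 45.5 and 0.89 FPKM and the lectin gene Clec10a at 25.6 and 0.23, whereas Arg1, arginase, stood at 0.22 and 21.8. Lysosome and autophagy genes had a median of -0.64 at 24 h against 0 h (percentile 3.04, and 0.05 with length matched). Of 22, 8 were at least 2-fold lower and 1 at least 2-fold higher. All 20 measured cytosolic ribosomal protein genes were at least 2-fold lower at 24 h than at 0 h (median -2.15), including Rpl3 with 641 and 70.2 FPKM. Copies and pseudogenes of these genes may share their reads. The list's median was -1.65 with the length trend removed. Among lists matched also on length it lay at percentile 0.02 (random median -0.73). In total 1106 genes were at least 2-fold higher and 1424 at least 2-fold lower. With equal medians the counts were 1163 and 1321, and with the length trend removed 1057 and 1045. A pseudocount of 5 gave 715 and 841.

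Lipid metabolism is the subject named in the series title. Cholesterol synthesis genes were taken with other targets of SREBP2, a sterol-regulated transcription factor. Their median difference from 0 h was -0.39 at 4 h (percentile 88.2, random median -0.71). At 24 h it was -1.04, below all random lists (median -0.09), with 13 of 24 at least 2-fold lower. Fdps, a farnesyl diphosphate synthase, was at 45.8 FPKM at 0 h, 33.0 at 4 h and 10.8 at 24 h. At 4 h the isomerase gene Idi1 (15.4 FPKM at 0 h and 35.9 at 4 h) was at least 2-fold higher than at 0 h, and Dhcr7 (13.4 and 1.90) was the lowest member. Between 4 h and 24 h the list had a median of -0.71, below all random lists (median 0.54), with 9 of 24 at least 2-fold lower at 24 h, among them Idi1 (35.9 and 6.69 FPKM) and Cyp51 (21.9 and 4.72). Mvk, mevalonate kinase, went the other way (1.55 and 4.71).

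Targets of LXR, the receptor for oxysterols, and genes of cholesterol efflux had a median of -0.99 at 4 h against 0 h (percentile 12.4) and -0.04 at 24 h (percentile 57.6). Between 4 h and 24 h their median was 1.24, at percentile 99.9 (random median 0.36), and 6 of 12 were at least 2-fold higher at 24 h. With libraries centred it was 0.71, and with the length trend removed 0.73. Scd2, a desaturase, stood at 9.01 FPKM at 0 h, 0.97 at 4 h and 20.6 at 24 h, the exporter gene Abcg1 at 48.9, 7.98 and 37.5, and Nr1h3, which encodes LXR alpha, at 43.0, 15.9 and 67.3. Apoe was at 18036, 8270 and 4694 FPKM. The exporter gene Abca1 had 11.2 FPKM at 0 h, 10.4 at 4 h and 33.4 at 24 h.

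Lipid uptake and storage genes had a median of -1.35 at 4 h (percentile 0.05) and -1.28 at 24 h, below all random lists, with 10 of 19 at least 2-fold lower and 6 at least 2-fold higher at 24 h. The 4 h median was -0.77 with libraries centred on the median gene and -0.40 with the length trend removed, and as means of members the values were -0.67 at 4 h and -0.64 at 24 h. Beside Lpl, the monoglyceride lipase gene Mgll was at 37.7 FPKM at 0 h and 1.28 at 24 h, and Pparg, a nuclear receptor that drives lipid storage, at 36.9 and 1.51. The acyl-CoA synthetase gene Acsl1 went the other way (9.82 and 242), as did the scavenger receptor gene Msr1 (45.1 and 425). Fatty acid oxidation genes had a median of -1.18 at 4 h (percentile 2.37, and 13.9 with length matched) and -0.87 at 24 h (percentile 0.02, and 0.15 with length matched). None of the 20 was at least 2-fold higher at either time, and 8 were at least 2-fold lower at 24 h, including Etfb, an electron transfer flavoprotein (63.3 and 10.1 FPKM), and the thiolase gene Acaa2 (29.7 and 7.18). Between 4 h and 24 h this list had a median of 0.09 against 0.49 for random lists (percentile 2.97, and 0.85 with length matched). The sign of this median turned under each of the other scalings. Fatty acid synthesis and desaturation genes lay inside the range of random lists, with medians of -0.95 at 4 h (percentile 18.9) and -0.43 at 24 h (percentile 8.29). Fads1, a desaturase, stood at 33.7 FPKM at 0 h, 4.54 at 4 h and 15.4 at 24 h, and Me1, malic enzyme, at 0.70, 0.36 and 5.20. From 4 h to 24 h their median was 0.58 (percentile 63.5). Eicosanoid genes went both ways, with 5 of 16 at least 2-fold higher and 8 lower at 4 h. Their medians were -0.94 at 4 h (percentile 16.0) and 0.20 at 24 h (percentile 91.2) and their means 0.55 and 0.62, with Ptges, a prostaglandin E synthase, at 1.27 FPKM at 0 h, 52.5 at 4 h and 173 at 24 h. Sphingolipid genes had medians of -0.41 (percentile 66.0) and -0.14 (percentile 42.4), with Cerk, ceramide kinase, at 99.2, 3.72 and 40.1 FPKM.

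**Figure D3:**
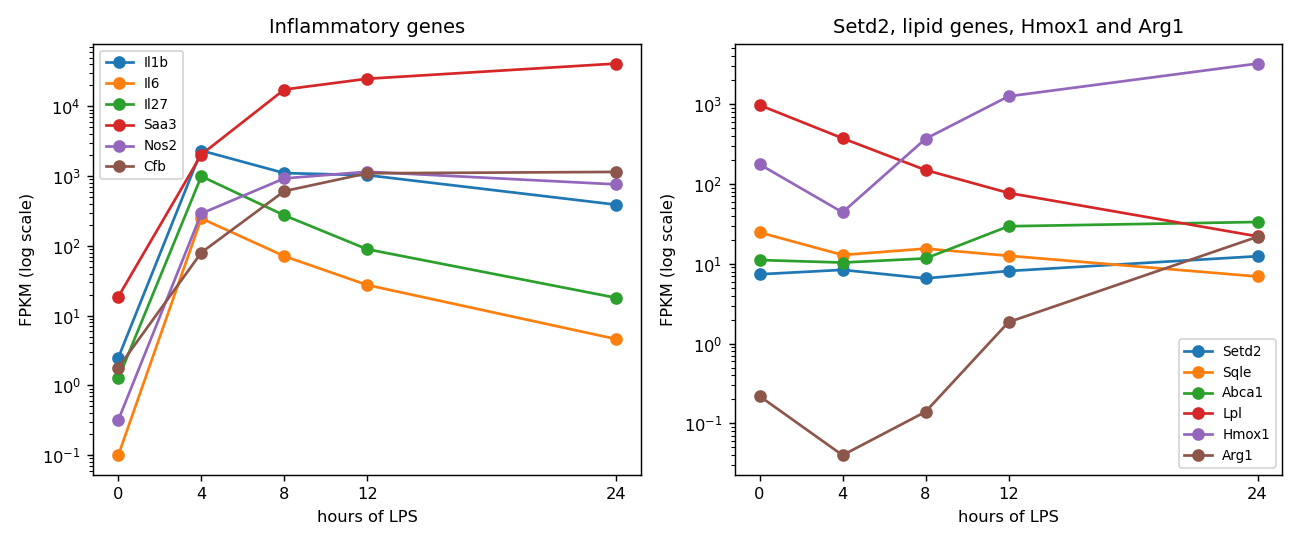
FPKM (vertical axis, log scale) of single genes in each library by hours in LPS (horizontal axis); each line is a gene and each point 1 library. Il6 stands at 247 FPKM at 4 h and 4.61 at 24 h, Saa3 at 2036 and 40998, and Setd2 lies between 6.57 and 12.45 in all 5 libraries.

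The comparison of 24 h with 4 h addresses the part of the course after the early response. Whether this part is resolution of inflammation was not tested. The cytokine and chemokine lists had negative medians at 24 h against 4 h, while the glycolysis, hypoxia and antioxidant lists had positive ones. The cytokine list had a median of -2.68, below all random lists (median 0.27), and 13 of 16 were at least 2-fold lower. Il27 stood at 993 FPKM at 4 h and 18.0 at 24 h, Il6 at 247 and 4.61, Il12b at 376 and 7.62, and Tnfsf15, of the TNF family, at 144 and 2.80. Edn1 (342 and 8.36), Ngp (39.0 and 0.28) and the chemokine gene Ccl3 (5651 and 200) also had large negative differences. Chemokines (median -1.47) and negative regulators of TLR signalling (-1.52) were below all random lists as well, with Cxcl1 at 104 and 3.34 FPKM and Il10 at 140 and 8.73. Immediate early genes had a median of -0.66 (percentile 0.02). Interferon-stimulated genes had a median of -0.33 (percentile 11.2) with 19 of 30 within 2-fold, and went both ways, with Gbp5 at 1113 and 189 FPKM and Bst2, tetherin, at 291 and 1249. Genes of MHC class II and costimulation had a median of -1.30, below all random lists, with Cd40 at 749.9 and 62.1 FPKM and the adhesion molecule gene Icam1 at 977 and 154. Against 0 h this list went both ways, with 5 of 12 at least 2-fold higher and 1 lower at 4 h, and 3 higher and 5 lower at 24 h. Its median was 0.06 at 4 h (percentile 85.4) and -0.66 at 24 h (percentile 4.10), and its mean 1.46 and 0.15.

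Genes higher at 24 h than at 4 h were led by Hmox1 (44.2 and 3228 FPKM), Tgfbi, a matrix protein gene (7.04 and 437), Ly6a (12.9 and 541), Ly6i (1.64 and 88.0), Gm5150 (0.60 and 49.6), Rab7b (1.65 and 64.7), Tmem104 (1.51 and 54.8) and Arg1 (0.04 and 21.8). Ly6a and Ly6i are near copies and their split is uncertain. Glycolysis genes had a median of 2.04 and 12 of 18 were at least 2-fold higher, among them Slc16a3 (27.3 and 230.0) and Tpi1 (82.3 and 629.9). NRF2 targets (median 1.58) and hypoxia-response genes (1.85) lay above all random lists too, with Gclm, a subunit of the glutathione-synthesis enzyme, at 14.3 and 136 FPKM. Antimicrobial and acute-phase genes had a median of 0.65 (percentile 99.8), with Hp, haptoglobin, at 12.0 and 274, and lysosome and autophagy genes of 0.58 (percentile 99.9), with Sqstm1 at 378 and 996. These 2 medians were 0.12 and 0.045 with libraries centred on the median gene. They were slightly negative with the length trend removed (-0.01 and -0.03), which also centres the libraries. Among random lists matched also on length both lay at percentile 99.8. Stress-response genes of the unfolded protein and integrated stress pathways had a median of 0.82 (percentile 98.9), and of 0.29 when centred and 0.36 with the length trend removed, with Ddit3 at 4.73 and 52.6 FPKM. Alternative activation markers (median -0.88) and efferocytosis genes (-0.89) were below all random lists. Ribosomal protein genes had a median of -0.97 (percentile 0.12), with 9 of 20 at least 2-fold lower.

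Overall counts between 4 h and 24 h were 2448 genes at least 2-fold higher and 802 lower (75.3% higher), against 876 and 1572 (35.8%) with libraries centred on the median gene. Of the 1197 genes at least 2-fold higher at 4 h than at 0 h, 695 were still at least 2-fold higher at 24 h, 489 lay within 2-fold and 13 were lower. Of the 3729 lower at 4 h, 1167 were still lower, 2513 lay within 2-fold and 49 were higher. With libraries centred, which changes the genes chosen, 1016 of the genes higher at 4 h lay within 2-fold at 24 h, and of those lower at 4 h, 662 were still lower and 919 lay within 2-fold. Because the 0 h and 4 h libraries chose these genes, chance extremes in them favour such a return. Among 6528 genes whose highest and lowest libraries differed at least 2-fold, 3567 had their highest value at 0 h, 823 at 4 h, 383 at 8 h, 489 at 12 h and 1266 at 24 h, and 3096 had their lowest at 4 h. With libraries centred, of the genes then at least 2-fold apart, 2170 had their highest value at 0 h, 1480 at 4 h, 649 at 8 h and 558 at 24 h, so that more had it at 4 h than at 24 h, and 1267 had their lowest at 4 h.

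Among the stimulated libraries, fewer genes were 2-fold apart between adjacent times than between 4 h and 24 h. From 4 h to 8 h, 512 genes were at least 2-fold higher and 380 lower, or 367 and 489 with libraries centred on the median gene. These counts were 1019 and 555 with a pseudocount of 0.1, and 199 and 194 with a pseudocount of 5. Haptoglobin (Hp, 12.0 and 149 FPKM), Gm15056 (0.76 and 14.6) and Saa3 (2036 and 17416) were the highest, and Errfi1, a feedback inhibitor of EGF receptor signalling (48.4 and 3.23), and the aggrecanase gene Adamts4 (17.6 and 0.59) were among the lowest. From 8 h to 12 h, 253 were higher and 92 lower, or 138 and 152 when centred. A pseudocount of 0.1 gave 594 and 140, and a pseudocount of 5 gave 75 and 51. Egln3 (1.78 and 12.7 FPKM) and the heat shock genes Hspa1a (15.9 and 83.6) and Hspa1b (11.1 and 52.8), near copies whose reads cannot be assigned with certainty, were the highest, and Gfi1, a transcriptional repressor (22.2 and 3.59), Snn (20.6 and 4.04) and Cnn3, a calponin (24.9 and 6.23), the lowest. From 12 h to 24 h, 335 were higher and 343 lower, or 137 and 598 when centred. A pseudocount of 0.1 gave 634 and 463, and a pseudocount of 5 gave 97 and 198. Tgfbi (25.9 and 437 FPKM), the transporter gene Abcc3 (2.07 and 26.2) and Arg1 (1.86 and 21.8) were the highest, and the cytokine gene Il19 (17.1 and 0.51), Hdc, histidine decarboxylase (43.0 and 2.85), and Shisa3 (22.8 and 1.14) the lowest. From 0 h, 1180 genes were higher and 2831 lower at 8 h (1737 and 1519 when centred), and 1205 and 2107 at 12 h (1541 and 1348 when centred).

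Markers of cell types are given next. In libraries of whole cultures they cannot separate a change in cell makeup from altered expression within cells. Macrophage identity genes had medians of -0.86 at 4 h (percentile 10.7) and -0.54 at 24 h (percentile 13.4), and went both ways at 24 h, with Itgam at 64.0 and 320 FPKM and Trem2 at 1003 and 58.8. Of 9 measured neutrophil markers, 6 were at least 2-fold lower at 24 h than at 0 h. Their median was -1.31 (percentile 0.06, and -0.62 with the length trend removed), against -0.12 at 4 h (percentile 92.4). The 4 h median was 0.47 with libraries centred, 0.14 with equal totals and 1.04 with the length trend removed. With length matched the percentiles were 98.9 at 4 h and 0.38 at 24 h. S100a9 stood at 167 FPKM at 0 h, 159 at 4 h and 7.14 at 24 h, while Ly6g, a granulocyte surface marker with close paralogs, stood at 0.12, 0.19 and 3.71. Among dendritic cell markers 4 were measured: Itgax (44.0 at 0 h and 4.65 at 24 h), Batf3 (4.14 and 3.03), Ccr7 (1.20 and 9.13) and Fscn1 (1.95 and 8.57). Lymphoid markers had 1 measured member, Cd4 (8.38 and 1.10), mast cell and basophil markers 3, each under 10 FPKM, and erythroid markers 0. Stromal markers had 5 measured members, with a median of -0.42 at 4 h (percentile 84.7). Of 16 cell cycle genes 9 were at least 2-fold lower at 4 h than at 0 h, with a median of -1.08 (percentile 19.8), while 2 were at least 2-fold higher, with Mki67, a marker of proliferation, at 1.36 FPKM at 0 h and 20 at 4 h. Genes often used as references had medians of -0.86 at 4 h (percentile 14.6) and -0.83 at 24 h (percentile 2.68). With length matched these percentiles were 6.90 and 0.44. Eef1a1, a translation elongation factor, stood at 4387 FPKM at 0 h and 409 at 24 h.

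The sign or size of many list medians depended on the scaling. Removing the length trend also centred the libraries, so its values hold both changes. At 4 h against 0 h, the medians of the cholesterol synthesis, alternative activation, glycolysis, sphingolipid, stromal and neutrophil lists were negative as deposited (glycolysis -0.27) and positive with libraries centred on the median gene (glycolysis 0.31, cholesterol synthesis 0.20) and with the length trend removed. The H3K36 list turned positive when centred (0.39), and the hypoxia (0.14), stress-response (0.09) and respiratory chain (0.12) lists with the length trend removed. The other negative medians at 4 h were closer to 0 under both scalings, as for fatty acid oxidation (-0.60 and -0.37) and the cell cycle (-0.50 and -0.41). At 24 h against 4 h, the TLR component, MHC class I, TCA cycle, respiratory chain, cell cycle, eicosanoid, sphingolipid, fatty acid oxidation, lipid uptake, macrophage and stromal lists were positive as deposited and negative when centred (fatty acid oxidation -0.44, lipid uptake -0.29) and with the length trend removed, and the H3K36 list was negative only when centred (-0.02). At 24 h against 0 h, the LXR, immediate early and stromal medians lay within 0.1 of 0 and were negative as deposited and positive under the 3 other scalings. Other medians kept their sign but moved over 1.5-fold. At 24 h against 4 h these included, when centred and with the length trend removed, NRF2 targets (1.05 and 1.04), cholesterol synthesis (-1.24 and -1.26), ribosomal protein (-1.50 and -1.49), efferocytosis (-1.43 and -1.48), alternative activation (-1.41 and -1.51), immediate early (-1.19 and -1.23) and interferon-stimulated genes (-0.86 and -0.96), and with the length trend removed glycolysis (1.30). A shift common to all genes leaves the percentiles among random lists as they are.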

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

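The values were recomputed with 1 choice changed at a time, giving 1214 values under the alternatives. Of these, 1056 stayed within bounds, which were 1.5 times the reported value for counts, the 95% interval from resampled members for list medians and the 95% counting interval for Setd2. A list median could change sign and still stay within its bounds. A further 155 left these bounds, and 3 changed sign from a reported value outside the middle 95% of random lists or with a counting interval off 0. Those given here are every count, Setd2 value and median of the cytokine, interferon and 5 lipid lists that left its bounds, and those that changed sign, with the reported value in parentheses; the other 55 were medians of the other lists, 22 with the length trend removed (14 above and 8 below the reported value), 21 with libraries centred (11 above and 10 below), 6 with equal totals (5 above and 1 below), 3 with a filter of 5 FPKM (2 above and 1 below), 2 with a pseudocount of 5 (1 above and 1 below) and 1 with a pseudocount of 0.1 (below). Whether inside or outside the bounds, of 96 list medians 22 changed sign with libraries centred, 25 with the length trend removed and 9 with equal totals. Unless the construction of the alternative is named, the cause was not tested. With a pseudocount of 0.1, the number of genes higher was 1019 (512) at 8 h against 4 h, 594 (253) at 12 h against 8 h and 634 (335) at 24 h against 12 h, and that of genes lower was 140 (92) at 12 h against 8 h. The list median was 3.53 (2.21) for inflammatory cytokines at 24 h against 0 h. With a pseudocount of 5, which by construction shrinks the differences of low genes, the number of genes higher was 715 (1106) at 24 h against 0 h, 199 (512) at 8 h against 4 h, 75 (253) at 12 h against 8 h, 97 (335) at 24 h against 12 h and 839 (2448) at 24 h against 4 h, and that of genes lower was 1976 (3729) at 4 h against 0 h, 1537 (2831) at 8 h against 0 h, 1188 (2107) at 12 h against 0 h, 841 (1424) at 24 h against 0 h, 194 (380) at 8 h against 4 h, 51 (92) at 12 h against 8 h and 198 (343) at 24 h against 12 h. Genes with their highest value numbered 2105 (3567) at 0 h, 314 (489) at 12 h and 567 (1266) at 24 h, and those with their lowest 1534 (3096) at 4 h, 595 (1016) at 8 h and 276 (436) at 12 h. At 24 h the genes lower at 4 h numbered 674 (1167) still 2-fold apart and 1289 (2513) within 2-fold. The list median was 1.04 (2.21) for inflammatory cytokines at 24 h against 0 h. The Setd2 difference was 0.49 (0.68) at 24 h against 0 h. With libraries centred on the median gene, which by construction adds a constant to all differences of a comparison, the number of genes higher was 1903 (1197) at 4 h against 0 h, 138 (253) at 12 h against 8 h, 137 (335) at 24 h against 12 h and 876 (2448) at 24 h against 4 h, and that of genes lower was 1598 (3729) at 4 h against 0 h, 1519 (2831) at 8 h against 0 h, 1348 (2107) at 12 h against 0 h, 152 (92) at 12 h against 8 h, 598 (343) at 24 h against 12 h and 1572 (802) at 24 h against 4 h. Genes with their highest value numbered 2170 (3567) at 0 h, 1480 (823) at 4 h, 649 (383) at 8 h and 558 (1266) at 24 h, and those with their lowest 1267 (3096) at 4 h, 626 (1016) at 8 h and 1047 (593) at 24 h. At 24 h the genes higher at 4 h numbered 1016 (489) within 2-fold. At 24 h the genes lower at 4 h numbered 662 (1167) still 2-fold apart and 919 (2513) within 2-fold. The list median was -0.86 (-0.33) for interferon-stimulated genes at 24 h against 4 h, -1.24 (-0.71) for cholesterol synthesis at 24 h against 4 h, 0.045 (0.58) for fatty acid synthesis at 24 h against 4 h, -0.60 (-1.18) for fatty acid oxidation at 4 h against 0 h and -0.44 (0.093) for fatty acid oxidation at 24 h against 4 h. The Setd2 difference was 0.74 (0.16) at 4 h against 0 h, 0.31 (-0.15) at 8 h against 0 h and 0.42 (0.12) at 12 h against 0 h. With libraries rescaled to equal totals, the number of genes higher was 384 (253) at 12 h against 8 h, and that of genes lower was 600 (380) at 8 h against 4 h. The Setd2 difference was 0.41 (0.16) at 4 h against 0 h. With a filter of 5 FPKM, which by construction leaves fewer genes, the number of genes higher was 223 (335) at 24 h against 12 h and 1517 (2448) at 24 h against 4 h, and that of genes lower was 2431 (3729) at 4 h against 0 h and 1812 (2831) at 8 h against 0 h. Genes with their highest value numbered 2330 (3567) at 0 h and 773 (1266) at 24 h, and those with their lowest 1934 (3096) at 4 h and 632 (1016) at 8 h. At 24 h the genes lower at 4 h numbered 1561 (2513) within 2-fold. Removal of the gene length trend, given next, by construction also brings the libraries to a common median. With the gene length trend removed, an alternative chosen after seeing the data, the number of genes higher was 319 (512) at 8 h against 4 h, 131 (253) at 12 h against 8 h, 134 (335) at 24 h against 12 h and 804 (2448) at 24 h against 4 h, and that of genes lower was 1259 (3729) at 4 h against 0 h, 1310 (2831) at 8 h against 0 h, 1137 (2107) at 12 h against 0 h, 145 (92) at 12 h against 8 h, 565 (343) at 24 h against 12 h and 1557 (802) at 24 h against 4 h. At 24 h the genes higher at 4 h numbered 961 (489) within 2-fold. At 24 h the genes lower at 4 h numbered 466 (1167) still 2-fold apart and 775 (2513) within 2-fold. The list median was -0.96 (-0.33) for interferon-stimulated genes at 24 h against 4 h, -0.013 (0.65) for antimicrobial effectors at 24 h against 4 h, 0.44 (-0.39) for cholesterol synthesis at 4 h against 0 h, -1.26 (-0.71) for cholesterol synthesis at 24 h against 4 h, -0.31 (-0.95) for fatty acid synthesis at 4 h against 0 h, 0.084 (0.58) for fatty acid synthesis at 24 h against 4 h, -0.37 (-1.18) for fatty acid oxidation at 4 h against 0 h, -0.60 (-0.87) for fatty acid oxidation at 24 h against 0 h, -0.52 (0.093) for fatty acid oxidation at 24 h against 4 h, -0.25 (-0.99) for LXR targets at 4 h against 0 h, -0.39 (0.24) for lipid uptake and storage at 24 h against 4 h and -0.032 (0.58) for lysosome and autophagy at 24 h against 4 h. The Setd2 difference was 0.28 (0.68) at 24 h against 0 h. Without the 0 h library genes with their highest value numbered 251 (383) at 8 h and 2469 (1266) at 24 h, and those with their lowest 599 (1016) at 8 h and 275 (436) at 12 h. Without the 4 h library genes with their highest value numbered 773 (383) at 8 h, and those with their lowest 2451 (1016) at 8 h. Without the 8 h library genes with their lowest value numbered 792 (436) at 12 h. Without the 12 h library genes with their highest value numbered 585 (383) at 8 h. Without the 24 h library genes with their highest value numbered 896 (489) at 12 h, and those with their lowest 704 (436) at 12 h. List medians without each member in turn and with no filter stayed within their bounds, as did every count with no filter. Leaving out 1 member could hardly move a median outside an interval resampled from the same members. As means of the members the values also stayed within these bounds, which are wide, but of 96 values 28 moved over 1.5-fold and 5 changed sign. Those 5 were eicosanoid genes 0.55 (-0.94), glycolysis 0.17 (-0.27) and stromal markers 0.20 (-0.42) at 4 h against 0 h, MHC class II 0.15 (-0.66) at 24 h against 0 h, and stromal markers -0.25 (0.091) at 24 h against 4 h. No paired analysis was possible because each time point was 1 library. Depth limits low genes, since 1 FPKM on a 1 kb transcript stands for about 19 reads, with a 95% Poisson interval of 11.4 to 29.7.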

Other observations

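The tests of the gene length trend at 0 h, of the differences that gene lengths give between 4 h and 24 h and of the share of cholesterol synthesis members were chosen after the result was seen, as were the gene families and the members named from them. The tests of the share of reads, of ribosomal protein genes without the highest genes and of cholesterol synthesis genes against lists matched on length were set before their results. Poly(ADP-ribose) polymerase genes (Parp), 12 of which were measured, had a median log2 difference from 0 h of 1.51 at 4 h and 1.96 at 24 h, positive under all 3 other scalings. At 4 h 7 were at least 2-fold higher and 4 lower, and at 24 h 7 were higher and 1 lower. Parp14 stood at 22.6 FPKM at 0 h, 524 at 4 h and 233 at 24 h, and Parp12 at 21.1, 210.1 and 129, whereas Parp1, a DNA repair enzyme, stood at 25.01, 8.13 and 11.0. Caspase genes (Casp, 8 measured) had medians of 1.17 at both times, also positive under the other scalings (1.75 and 1.78 at 4 h with libraries centred and with the length trend removed). Of the 8, 4 were at least 2-fold higher and 2 lower at 4 h, and 5 higher and 0 lower at 24 h. The inflammatory caspase gene Casp4 stood at 12.2, 145 and 107 FPKM, and Casp9, which initiates apoptosis, at 12.9, 1.54 and 7.82.

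All 8 measured S100a calcium-binding protein genes were at least 2-fold lower at 24 h than at 0 h, with a median of -2.39, negative under each scaling. Of these, S100a8 and S100a9 are among the 9 neutrophil markers, 6 of which were also at least 2-fold lower at 24 h (median -1.31, and -0.62 with the length trend removed). At 4 h the S100a median was -1.01, and 0.15 with the length trend removed. Autophagy genes (Atg, 17 measured) had a median of -1.21 at 4 h against 0 h, with 10 at least 2-fold lower, where the median of all genes was -0.70. This lay inside the middle 95% of random lists (percentile 4.32), and was -0.63 with libraries centred and -0.40 with the length trend removed. At 24 h against 4 h their median was 1.16 (percentile 99.7), with 9 at least 2-fold higher, and 0.62 and 0.63 under these scalings. Atg7 stood at 22.5 FPKM at 0 h, 5.91 at 4 h and 10.9 at 24 h, and Atg5 at 20.3, 8.17 and 28.6. TNF receptor family genes (Tnfrsf, 13 measured) had medians of 0.21 at 4 h, with 3 at least 2-fold higher and 3 lower, and 1.13 at 24 h, with 7 higher and 1 lower. The 4 h median was 0.79 with libraries centred and 0.97 with the length trend removed, with Tnfrsf26 at 10.6, 1.48 and 36.3 FPKM.

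The median gene was lower at 4 h than at 0 h by -0.70. A candidate explanation is that induced genes took reads from the rest. Genes at least 2-fold higher at 4 h took 41.5% of length-weighted FPKM at 4 h and 6.11% at 0 h. This alone gives -0.68 for the others, though these genes were picked by that difference. The -0.68 was computed without a pseudocount, while -0.70 is on log2(FPKM + 1). With a pseudocount of 0.1 the median gene was at -0.81, so the closeness depends on the scale. The share calculation gives -0.53 at 24 h, where the median gene was at -0.11. It thus does not account for the median at every time. A loss of read share would lower the FPKM of all other genes by the same factor. Yet at 4 h the median difference from 0 h was -1.29 for the group of shortest genes and -0.06 for the longest. A uniform loss alone does not give this spread by length. A length trend between the 0 h library and the others cannot be told apart from an effect of LPS, since 0 h was 1 library; the longest 20% of genes had a median of -0.18 at 4 h.

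Ribosomal protein genes were lower at 24 h than at 4 h, with a median of -0.97. Between these libraries genes differed little by length, and genes of the lengths of the list's members differed from the median of all genes by -0.065, against -1.46 for the list, which argues against a length trend. With the 20 genes that were among the 10 highest of a library left out and the rest rescaled, the median was -0.95, which argues against a few genes taking more of the total. Reads shared with pseudogenes stay open, and no biological explanation was tested.

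Cholesterol synthesis genes were lower and LXR targets higher at 24 h than at 4 h relative to random lists. Genes of the lengths of the cholesterol synthesis members differed from the median of all genes by 0.020, against -1.20 for the list, and genes of the lengths of the LXR targets by -0.0052, against 0.75, which argues against a length trend. Random lists matched on length could show nothing more, as there was hardly a trend to match. Sterols accumulating between these times may lower the one and raise the other, and 19 of 24 cholesterol synthesis members (79.2%) lay under the median of random lists. This test decides nothing, since it repeats the low median of the list and its bound of 80% was set after that median was seen. The level of sterols was not measured in the sources used here.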
